A study of Mus musculus with 4 samples.

How the data were processed

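Liver RNA of 4 female mice aged 11 weeks on the FVB background was sequenced, 2 wild-type (WT) mice and 2 mice labelled PA, which per the labels are hypomorphic for Pcca. Pcca encodes a subunit of propionyl-CoA carboxylase, and its loss in people causes propionic acidemia. The labels describe polyA RNA from frozen tissue and libraries made with a NEBNext kit. Groups and replicate numbers were taken from the sample titles, and the design text of the series calls the replicates biological.

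The deposited data held 2 files per library. One gave raw read counts per gene made by the authors with STAR, with separate columns without regard to strand, on the sense strand and on the opposite strand, as the layout of the deposited file shows. The other gave, per the file headers, expected counts, TPM and FPKM per gene from RSEM. The TPM and FPKM values deposited by the authors are normalised within a library and were not tested. STAR 2.7.6a, RSEM 1.3.3 and the genome build GRCm38 are named in the submitters' processing notes. The annotation release used for counting was not given in the sources used here. STAR's gene counts leave out reads that map to several places, and the RSEM expected counts share such reads out, so near-identical genes such as the Mup, Cyp3a and Gsta families can be undercounted in the first and misassigned in the second.

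The opposite-strand column held 97, 97.08, 96.98 and 96.96% of the stranded counts in WT replicates 1 and 2 and PA replicates 1 and 2. By a rule asking for over 80% in every library it was used as the main count. The 4 summary lines of each table, which name no gene, were left out of library sizes and tests. Together they held 29.6 and 31.1% of reads in the WT libraries and 34.3 and 28.1% in the PA libraries. Of the 55487 gene identifiers, 55227 matched GENCODE M21, an annotation of the same build, which gave symbols, positions and biotypes, and 260 did not match. Total gene counts of 25575016 to 30110400 per library put 3 counts at 0.0996 to 0.117 CPM. Intervals and floors computed from counts cover counting error only.

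Differential expression was tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalisation, the default filterByExpr filter and genotype as the only term. A prior count of 0.125 was used, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Standard errors are the log2 fold change divided by the square root of the F statistic. CPM values are given on TMM-scaled library sizes. For genes with 1 to 3 counts in a group, the fold is the ratio of summed counts with an exact binomial interval at the 95% level. For genes with 0 counts it is the ratio to an assumed 3 counts over the group, given with the lower limit of that interval. Fitted fold changes of such genes depend on the prior count.

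Before the data were examined, 43 gene lists were fixed, among them markers of other liver cell types, of blood and of pancreas. The 40 lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01 (a two-sided test) and adjusted over the lists. They were tested again with a correlation estimated from the residuals and with fry, where a call rests on the directional p. The named genes were also set by rule beforehand. They are Pcca and Pccb; the 10 called protein-coding genes with the largest fold change in each direction, with no overlap of CPM between groups and a mean of at least 1 CPM in the higher group; up to 4 members by smallest p of each list with a called member; and the 3 most abundant members of each cell type or RNA quality list. Predicted gene models and non-coding genes were left out of the ranking, which removed 8 higher and 14 lower calls. Of the genes the rule names, 1 is not reported here. Genes named outside this rule were chosen after their values were seen, and they stand in the examples of lists without a call and in the closing section. Lists of growth hormone induced genes and of fetal liver genes were added after the called genes had been seen.

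Replicates were checked for duplicate libraries with a chi-square test over genes with at least 20 counts in the pair. The statistic per degree of freedom was 46.3 for the WT pair and 135 for the PA pair, so neither pair agreed within sampling noise. The steps were tested on simulated counts for the 14411 tested genes of PA against WT, with 200 changed genes in each of 5 simulations. The test recovered 26% of genes changed by 1 on the log2 scale, 92.6% of those changed by 2 and 99.1% of those changed by 3, and 3.77% of calls were false. Every simulated gene took its dispersion from the fitted trend, the same in both groups. In the data the dispersion also varies between genes, and the PA pair agreed less closely than the WT pair. These percentages can therefore be better than those the test reaches on the data. A list shifted by 1 on the log2 scale was found by camera in 5 of 5 simulations, and in 0 of 5 with an estimated correlation. Each simulated gene was drawn independently of the others. In the data the estimated correlation was 0.391 for that list, cholesterol synthesis, and 0.988 for erythrocyte markers. The simulations therefore do not test the preset correlation. Alternatives covered other normalisations and filters, DESeq2 1.42.0, limma-voom, RSEM expected counts rounded to whole numbers, unstranded counts, a replicate block and leaving out each library. One alternative, leaving out mitochondrially encoded genes, was chosen after seeing the data.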

Results

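Polyadenylated RNA was measured in the livers of 4 female mice, 2 WT and 2 PA, all 11 weeks old. The PA mice are labelled hypomorphic for Pcca, which encodes a subunit of propionyl-CoA carboxylase, the mitochondrial enzyme that clears propionyl-CoA. The title of the series sets the work in the context of acylation of histone H4 and the transcriptional response to metabolic perturbation, and the comparison asks how liver transcripts differ between the genotypes. Gene counts summed to 29627033 and 25575016 in WT replicates 1 and 2 and to 25990553 and 30110400 in PA replicates 1 and 2. The first principal component of log CPM held 60.3% of the variance and placed both PA libraries on one side and both WT libraries on the other. The second held 25.0% and set the PA libraries far apart, at 31.0 and -39.3, with the WT libraries at -0.57 and 8.83. Correlations across genes were 0.984 between the WT libraries, 0.974 between the PA libraries and 0.952 to 0.965 between groups; genes are not independent replicates.

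Pcca itself (ENSMUSG00000041650, chromosome 14, 122534324 to 122891100, plus strand, GRCm38) was read at 60.3 and 58.9 CPM in the WT livers and at 34.2 and 47.4 CPM in the PA livers. Its log2 fold change was -0.55 with a standard error of 0.22 (edgeR quasi-likelihood test, adjusted p = 0.398), so the lower values did not pass the threshold. Pccb, which encodes the partner subunit, was at 134 ± 2.41 CPM in WT and 144 ± 6.74 CPM in PA (SD, n = 2 each; edgeR adjusted p = 0.896). A gene-level count does not tell a mutant transcript from a normal one, so these values are a limited check of the genotype labels.

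Among the genes that differed between PA and WT livers were genes expressed differently in male and female liver, major urinary proteins and enzymes of detoxification. Of 14411 genes tested, 117 passed an adjusted p of 0.05, 38 higher and 79 lower in PA. All 117 had an absolute log2 fold change over 1, and 90 of them were called in every fit that left out 1 library. The counts were 239 higher and 261 lower without PA replicate 2, 129 and 174 without PA replicate 1, 82 and 139 without WT replicate 2, and 50 and 105 without WT replicate 1. The share of calls that were higher was 32.5%, against 45.9% with no filter on low counts, 43% with DESeq2, 42.6% without PA replicate 1 and 47.8% without PA replicate 2. A fit without 1 library leaves 1 mouse in a group and takes its variation from the other group. Calls gained in such fits are therefore no added support. With 2 mice per group, the simulated test missed most genes changed by 1 on the log2 scale, so a gene that was not called is not shown to be unchanged.

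**Figure D1:**
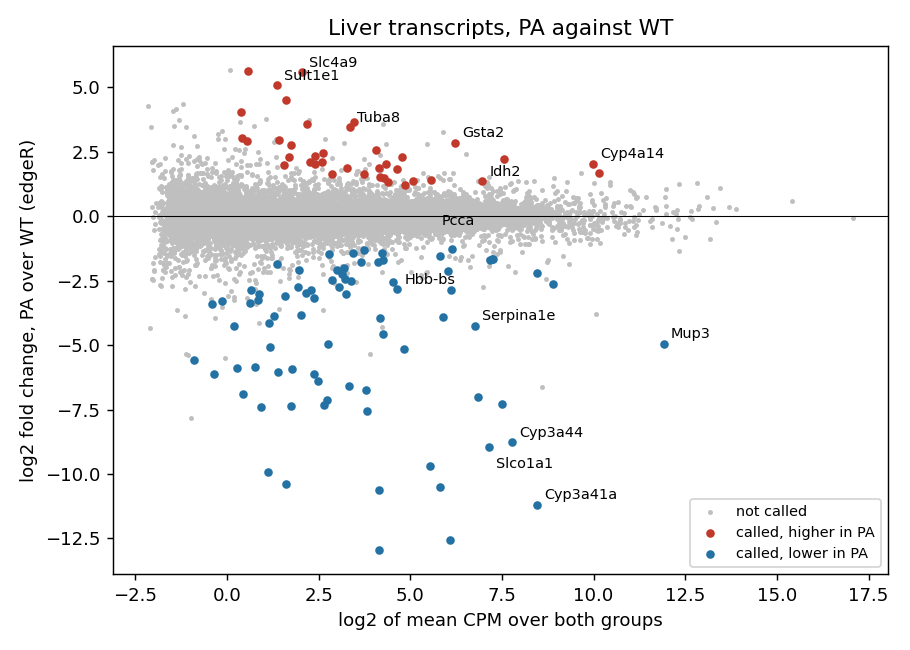
Log2 fold change of PA over WT against the log2 of the mean CPM over both groups, for 14411 tested genes; each point is a gene, red and blue points passed an adjusted p of 0.05 in edgeR. The 79 lower calls reach fold changes far larger in size than the 38 higher calls, and fitted values of genes with no or few PA counts depend on the prior count.

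The 10 largest falls among the ranked genes were in the Cyp3a and Mup gene clusters, apart from Slco1a1. Cyp3a41a, a cytochrome P450 expressed mainly in female liver, was at 700 ± 37.7 CPM in WT and 0.306 ± 0.290 CPM in PA (SD, n = 2 each; log2 fold change -11.19, standard error 0.61, edgeR adjusted p = 0.000535). Its neighbour Cyp3a44 (chromosome 5, 145773983 to 145805874) fell from 436 ± 31.8 to 0.996 ± 0.0199 CPM (log2 fold change -8.77). Cyp3a41b had 1971 counts over the WT libraries and 0 over the PA libraries, 646-fold lower if 3 PA counts are assumed (lower 95% counting limit 525). Major urinary proteins are pheromone-binding proteins secreted by the liver, encoded by a cluster on chromosome 4. Of 22 tested Mup genes and pseudogenes, 17 were called, all of them lower. Mup17 was at 111 ± 8.30 CPM in WT and 0.0757 ± 0.0595 CPM in PA, and Mup22 was at 93.0 ± 3.82 and 0.104 ± 0.0912 CPM (SD, n = 2). Mup15 had 7707 WT counts and 1 PA count, a ratio of 7580 with a 95% counting interval of 1360 to 299000. Mup18 had 1981 WT counts and 1 PA count, a ratio of 1950 (349 to 77000). Mup19 and Mup14 had 0 PA counts and were 114-fold and 78.3-fold lower if 3 PA counts are assumed (lower 95% counting limits 92.3 and 63.2). These families are near-identical copies and single members are uncertain. Summed over 49 Mup genes and pseudogenes, WT exceeded PA 26.9-fold in STAR counts and 43.5-fold in RSEM expected counts. In STAR counts most of the sum in each group came from Mup3 (log2 fold change -4.95), so that ratio mainly describes this gene. Summed over Cyp3a16, Cyp3a41a, Cyp3a41b and Cyp3a44, WT exceeded PA 434-fold in STAR counts and 1410-fold in RSEM expected counts, so the size of that fall differs between the 2 counts. Without PA replicate 1 and without PA replicate 2 the log2 fold changes were -12.69 and -10.41 for Cyp3a41a, -14.93 and -11.61 for Mup15, and -12.99 and -9.66 for Mup18. They were -11.51 and -9.83 for Mup17 and -9.07 and -11.05 for Mup22, and each stayed called.

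Genes with a known sex bias in liver fell as lists. Of 20 tested male-biased genes, 7 were called, all lower, 13 were lower and 2 higher when adjusted over the list alone, and the median log2 fold change was -1.66 (camera adjusted p = 4.01e-24, and adjusted p = 0.532 with an estimated correlation). Slco1a1, an organic anion transporter, fell from 284 ± 93.5 to 0.564 ± 0.297 CPM (log2 fold change -8.94, standard error 0.49; -9.63 without PA replicate 2, -6.85 in unstranded counts and -8.13 with RSEM counts). Serpina1e, a protease inhibitor of the alpha-1-antitrypsin family, fell from 206 ± 7.38 to 10.9 ± 5.97 CPM (log2 fold change -4.24; -4.95 without PA replicate 2). Ugt2b38 had a log2 fold change of -4.13 (-4.96 with RSEM counts), and Mup7 had 151 WT counts and 1 PA count, a ratio of 148 (26.2 to 5900; fitted log2 fold change -6.13 without PA replicate 1 and -9.19 without PA replicate 2). Of 28 tested female-biased genes, 6 were called lower and 2 higher, 13 were lower and 4 higher when adjusted over the list alone, and the median was -0.78 (camera adjusted p = 5.09e-17, and adjusted p = 0.532 with an estimated correlation). Besides the Cyp3a41 genes and Cyp3a44, Cyp3a16 fell from 358 ± 157 to 2.34 ± 2.13 CPM (log2 fold change -7.27; -8.72 without PA replicate 1, -6.54 without PA replicate 2 and -10.66 with RSEM counts). The female-biased genes did not move one way, since 9 of 28 had higher values in PA. Both medians were the same with members at 0 or few PA counts set to their bound. Only 1 member of each list was set in this way, and it lay far below the median with either value. The medians could therefore not have moved, and their agreement is no added support. Cyp4a14, an omega-hydroxylase of fatty acids induced through PPARA, rose from 396 ± 63.9 to 1638 ± 205 CPM (log2 fold change 2.05, edgeR adjusted p = 0.0295; 0.0605 without WT replicate 1 and 0.12 without WT replicate 2).

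**Figure D2:**
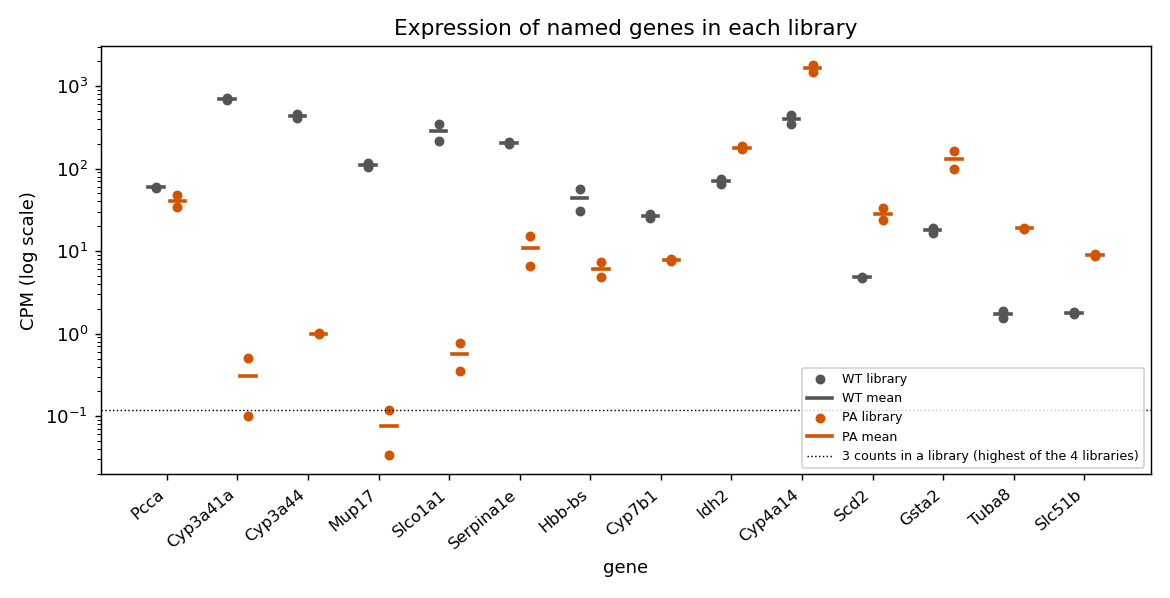
CPM on a log scale of 14 genes in each library; points are libraries (2 WT in grey, 2 PA in orange), short bars are group means, and the dotted line marks 3 counts in the library with the highest such limit. Cyp3a41a averaged 700 CPM in the WT livers and 0.306 CPM in the PA livers, while Tuba8 averaged 1.71 CPM in WT and 18.8 CPM in PA.

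The 10 largest rises among the ranked genes included glutathione S-transferases and transporters. Gsta1 and Gsta2, which conjugate glutathione to electrophiles, rose from 0.252 ± 0.0330 to 5.83 ± 1.97 CPM and from 17.9 ± 1.71 to 130 ± 44.1 CPM (log2 fold changes 4.52 and 2.86, edgeR adjusted p = 0.00602 and 0.00871). These genes are close paralogs that can share reads, so the values of each are uncertain. Slc4a9, an anion exchanger, had the highest log2 fold change of the ranked genes, 5.60 with a standard error of 0.82, from 0.170 ± 0.148 to 8.12 ± 6.29 CPM. It was 4.47 without PA replicate 1, 6.24 without PA replicate 2, 6.87 without WT replicate 2 and 4.85 without WT replicate 1, and limma-voom did not call it (adjusted p = 0.118). Sult1e1, the estrogen sulfotransferase, rose from 0.140 ± 0.0320 to 5.04 ± 3.37 CPM (log2 fold change 5.10; 4.19 without PA replicate 1; limma-voom adjusted p = 0.0857). Tuba8, an alpha-tubulin, rose from 1.71 ± 0.254 to 18.8 ± 0.718 CPM (log2 fold change 3.45, standard error 0.24). The stearoyl-CoA desaturase Scd2 had a log2 fold change of 2.57, Pls1 of 2.75 and Sema3b of 3.04, the last 2.12 in unstranded counts. Abcc4, an export pump for organic anions that include bile acids, rose from 1.89 ± 0.499 to 10.4 ± 3.51 CPM (log2 fold change 2.47); it lies 3.83 Mb from Pcca.

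The lists of drug and antioxidant response rose by camera with the preset correlation. Both hold Gsta2 and Gstm3, so they are not separate evidence. Their mean log2 fold changes, 0.58 and 0.61, lay above their medians, so a few members weighed heavily. Of 23 tested NRF2 antioxidant genes, 2 were called higher and 0 lower, 6 were higher and 1 lower when adjusted over the list alone, and the median was 0.26 (camera adjusted p = 2.43e-05, and adjusted p = 0.532 with an estimated correlation). The 2 were Gsta1 and Gsta2; Nqo1 had a log2 fold change of 1.18 (edgeR adjusted p = 0.0586) and Gstm3 of 2.42 (0.0622; 1.74 without PA replicate 1). DESeq2 called both. Without PA replicate 2 the log2 fold changes were 1.28 for Nqo1 and 2.88 for Gstm3. Of 24 CAR and PXR drug metabolism genes, 2 were called, Gsta2 and Abcc4, and 3 were higher when adjusted over the list alone (median 0.21, camera adjusted p = 0.000186, and adjusted p = 0.551 with an estimated correlation). Of 23 genes of bile acid synthesis and transport, Slc51b and Abcc4 were called higher and Cyp7b1 lower, with 4 higher and 1 lower when adjusted over the list alone. Slc51b, part of a basolateral bile acid exporter, rose from 1.77 ± 0.0556 to 8.90 ± 0.314 CPM. Cyp7b1, the oxysterol hydroxylase of the alternative bile acid pathway, fell from 26.9 ± 1.96 to 7.90 ± 0.294 CPM (log2 fold change -1.77). Cyp7b1 is also among the lower calls of the male-biased list, and Abcc4 among those of the drug metabolism list, so these calls are counted again. The bile acid list as a whole was not called (camera adjusted p = 0.626). Its median was -0.15 while its mean was 0.08.

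Lists of mitochondrial metabolism and sterol synthesis shifted up by small amounts. Of 23 genes of the TCA cycle and anaplerosis, 19 had higher values and 1 was called, with 1 higher when adjusted over the list alone (median 0.32, camera adjusted p = 0.00131, and adjusted p = 0.551 with an estimated correlation). That gene was Idh2, the mitochondrial NADP-dependent isocitrate dehydrogenase, which rose from 70.2 ± 7.57 to 180 ± 8.56 CPM (log2 fold change 1.36, edgeR adjusted p = 0.0474; 0.389 without WT replicate 1 and 0.168 without WT replicate 2). It was not called with RSEM counts (0.0533), limma-voom (0.0509) or the CPM filter (0.05). Of 34 nuclear genes of oxidative phosphorylation, 32 had higher values, 6 had an edgeR unadjusted p under 0.05, and 0 were called by edgeR, DESeq2, limma-voom or when adjusted over the list alone (median 0.24, camera adjusted p = 0.00423, 0.211 without PA replicate 1, and adjusted p = 0.644 with an estimated correlation). Of 26 cholesterol synthesis genes, 24 had higher values, 9 had an edgeR unadjusted p under 0.05, and 0 were called by edgeR, DESeq2, limma-voom or when adjusted over the list alone (median 0.51, camera adjusted p = 6.07e-05, 0.0911 without PA replicate 2, and adjusted p = 0.63 with an estimated correlation). Glycine, serine and one-carbon metabolism had 24 tested genes, 19 with higher values, 3 at an edgeR unadjusted p under 0.05, 0 called (DESeq2 1, limma-voom 0) and 1 higher when adjusted over the list alone (median 0.26, camera adjusted p = 0.0184, and adjusted p = 0.551 with an estimated correlation). Its camera adjusted p was 0.194 without WT replicate 2 and 0.0568 without PA replicate 2. The ATF4 stress response list shares Psat1, Psph, Mthfd2, Shmt2 and Cth with the one-carbon list, so these lists are not separate evidence. The ATF4 list had 26 tested genes and 1 called, Vldlr, the very low density lipoprotein receptor, with 3 higher when adjusted over the list alone (median 0.27, camera adjusted p = 0.0152, and adjusted p = 0.551 with an estimated correlation). Vldlr had a log2 fold change of 1.89 (edgeR adjusted p = 0.0385; 0.0539 without WT replicate 1), and the camera adjusted p of the list was 0.0629 without WT replicate 2 and 0.222 without PA replicate 1. Asns, which makes asparagine, had a log2 fold change of 3.67 (edgeR adjusted p = 0.0899), with 3.61 CPM in PA replicate 1 and 1.11 CPM in PA replicate 2. The log2 fold change of Asns was 2.61 without PA replicate 1, 4.30 without PA replicate 2 and 4.13 without WT replicate 2. DESeq2 called Asns (adjusted p = 0.000333).

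Lists fixed as markers of RNA quality differed between the groups too, though RNA quality itself was not tested. Mitochondrially encoded genes took 6.90 and 7.38% of counts in WT and 13.6 and 9.0% in PA. Reads mapped to several places made up 9.11 and 9.42% in WT, 13.5% in PA replicate 1 and 9.19% in PA replicate 2. All 13 listed mitochondrial transcripts had a positive log2 fold change, 1 was called and 9 were higher when adjusted over the list alone (median 1.11, camera adjusted p = 1.66e-10, and adjusted p = 0.551 with an estimated correlation). The called one, mt-Nd6, rose from 10.9 ± 1.31 to 38.6 ± 7.25 CPM, and it was not called in unstranded counts (0.105) or with RSEM counts (0.127). The abundant mt-Co1 had a log2 fold change of 0.61 (edgeR adjusted p = 0.59), and mt-Atp8 of 3.58 (0.0725). The transcript mt-Cytb was at 13377 and 13703 CPM in WT, 21480 CPM in PA replicate 1 and 11697 CPM in PA replicate 2, the last below both WT libraries. The value of mt-Atp8 was 1.90 with RSEM counts (edgeR adjusted p = 0.0805). It was 2.96 without WT replicate 1, 4.58 without WT replicate 2, 2.63 without PA replicate 1 and 4.15 without PA replicate 2. Of 17 immediate early genes, 16 had higher values, 6 had an edgeR unadjusted p under 0.05, 0 were called (DESeq2 2, limma-voom 0) and 2 were higher when adjusted over the list alone (median 0.72, camera adjusted p = 0.000326, 0.168 without PA replicate 1, and adjusted p = 0.63 with an estimated correlation). Dusp1 was at 12.7 and 13.6 CPM in WT, 49.9 CPM in PA replicate 1 and 17.2 CPM in PA replicate 2. Its log2 fold change of 1.35 was 0.39 without PA replicate 1 and 1.92 without PA replicate 2, and DESeq2 called it (adjusted p = 0.0377). Without the mitochondrially encoded genes, a fit chosen after seeing the data, 46 genes were higher and 92 lower.

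Lists of interferon-stimulated genes, cell cycle genes and markers of macrophages, B cells and red blood cells were lower in PA. Of 32 interferon-stimulated genes, 31 had lower values, 22 had an edgeR unadjusted p under 0.05, 0 were called (DESeq2 11, limma-voom 0) and 20 were lower when adjusted over the list alone (median -0.77, camera adjusted p = 5.03e-16, and adjusted p = 0.551 with an estimated correlation). Ifit1 had a log2 fold change of -1.59 (edgeR adjusted p = 0.0552) and Ifi27 of -1.63 (0.0566), and DESeq2 called both. edgeR called Ifit1 with library sizes only (adjusted p = 0.0488) and in unstranded counts (0.0491). The log2 fold change of Ifit1 was -1.55 and -1.62 without WT replicates 1 and 2, and -1.28 and -1.98 without PA replicates 1 and 2. That of Ifi27 was -1.66 without WT replicate 2, -1.315 without PA replicate 1 and -2.04 without PA replicate 2. Of 16 Kupffer cell and macrophage markers, 13 had lower values, 8 had an edgeR unadjusted p under 0.05, 0 were called (DESeq2 4, limma-voom 0) and 7 were lower when adjusted over the list alone (median -0.65, camera adjusted p = 1.67e-05, and adjusted p = 0.63 with an estimated correlation). Clec4f was at 187 ± 29.8 CPM in WT and 94.2 ± 25.3 CPM in PA, Ctsc at 189 ± 39.4 and 77.1 ± 38.0 CPM, and Slc40a1 at 137 ± 14.4 and 146 ± 9.51 CPM. Of 9 B cell markers, 8 had lower values, 4 had an edgeR unadjusted p under 0.05, 0 were called (DESeq2 1, limma-voom 0) and 4 were lower when adjusted over the list alone (median -1.03, camera adjusted p = 0.000149, and adjusted p = 0.532 with an estimated correlation), with Ighm at 9.46 ± 2.66 and 2.52 ± 1.39 CPM. Without PA replicate 2, the log2 fold changes of Ighm, Ctsc and Clec4f were -2.63, -1.91 and -1.30. Without PA replicate 1, those of Ctsc and Clec4f were -0.85 and -0.74, and Ighm was at -2.15 without WT replicate 2. Of 5 erythrocyte markers, 2 were called and 4 were lower when adjusted over the list alone (median -2.50, camera adjusted p = 1.66e-10, and adjusted p = 0.551 with an estimated correlation). Hbb-bs, a beta globin, fell from 43.7 ± 18.9 to 6.12 ± 1.72 CPM and Hbb-bt from 7.91 ± 3.19 to 0.996 ± 0.353 CPM, the latter not called by limma-voom (0.0524). Hba-a1 and Hba-a2 had log2 fold changes of -2.50 and -2.47 (edgeR adjusted p = 0.107 and 0.122) and Alas2 of -0.60. The values of Hba-a1 and Hba-a2 were -1.87 and -1.80 without WT replicate 1 and -3.29 and -3.19 without PA replicate 2. Both were called by DESeq2 (adjusted p = 0.000596 and 0.00525). Of 21 cell cycle genes, 16 had lower values, 6 lower and 2 higher ones had an edgeR unadjusted p under 0.05, 0 were called (DESeq2 1 higher and 1 lower, limma-voom 0), and 4 were lower and 1 higher when adjusted over the list alone (median -0.35, camera adjusted p = 0.0166, 0.313 without WT replicate 1, and adjusted p = 0.551 with an estimated correlation). In all, 16 of the 40 lists passed with the preset correlation, 9 higher and 7 lower. None passed with an estimated correlation, where 3 lists had an unadjusted p under 0.05, or with fry, where 8 did.

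**Figure D3:**
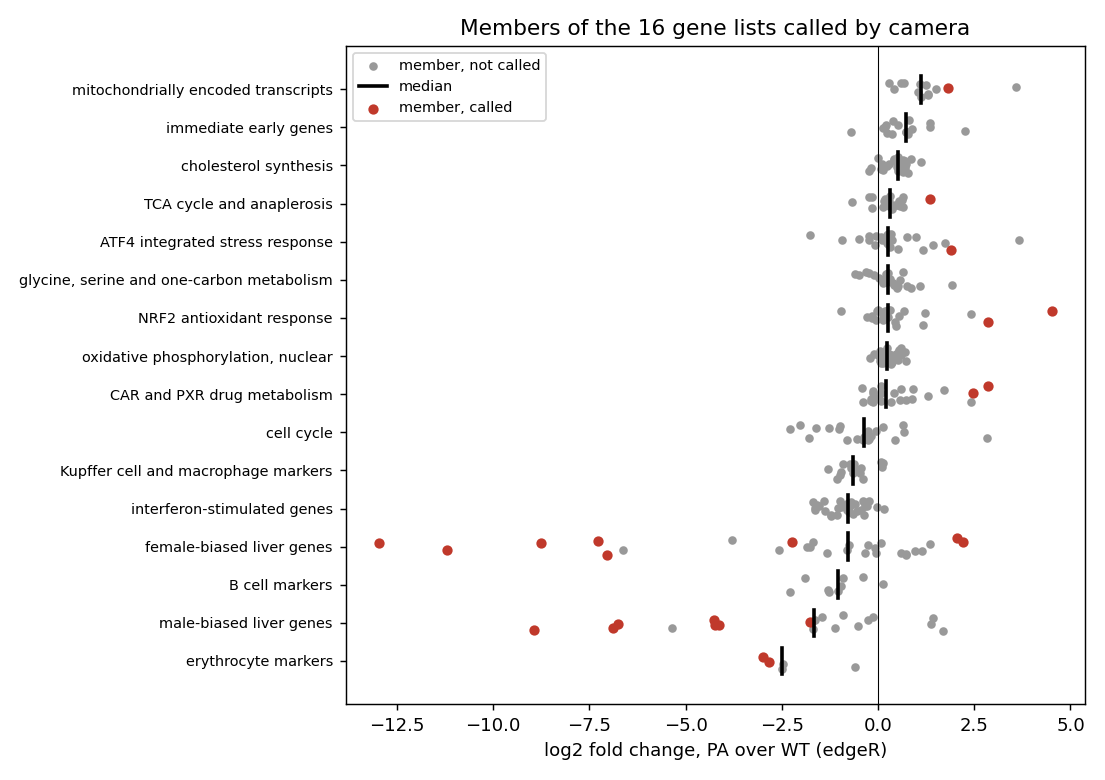
Log2 fold change of PA over WT of each tested member of the 16 lists called by camera, on a linear axis; points are genes, red points passed an adjusted p of 0.05 over all genes, and the black bar is the list's median. Medians lay between -2.50 and 1.11, and the lists of erythrocyte markers, male-biased genes, B cell markers and mitochondrially encoded transcripts were the only ones beyond 1 in size.

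Lists of the pathways nearest to the altered enzyme were not called. The propionate and methylmalonate pathway had 18 tested genes, 12 with higher values, 2 higher and 2 lower at an edgeR unadjusted p under 0.05 and 0 called by edgeR, DESeq2 or limma-voom, with 1 higher and 1 lower when adjusted over the list alone (median 0.09, camera adjusted p = 0.56). Branched-chain amino acid catabolism (median 0.03, camera adjusted p = 0.5), the urea cycle (0.09, 0.372) and mitochondrial fatty acid oxidation with ketogenesis (0.03, 0.722) had 0 called genes by edgeR or limma-voom and 0 when adjusted over the list alone, with 1, 3 and 1 at an edgeR unadjusted p under 0.05 and 0, 2 and 0 called by DESeq2. PPARA targets had 1 called gene of 24, Cyp4a14 (median 0.16, camera adjusted p = 0.324), with 2 higher and 1 lower when adjusted over the list alone. Cyp4a14 is also counted among the higher calls of the female-biased list. Fabp1, the liver fatty acid binding protein, was at 7419 ± 149 CPM in WT and 2929 ± 711 CPM in PA (edgeR adjusted p = 0.14, DESeq2 adjusted p = 7.02e-05). Its log2 fold change of -1.34 was -1.61 without PA replicate 1 and -1.11 without PA replicate 2. Carnitine and acyl-CoA handling had a median of -0.08 (camera adjusted p = 0.617) and 0 members called by edgeR or limma-voom (2 higher and 3 lower at an edgeR unadjusted p under 0.05, DESeq2 1 and 3), with 1 higher and 3 lower when adjusted over the list alone. Histone acetyltransferases and MOF complexes, which include enzymes that acetylate histone H4, had 24 tested genes and 0 called by edgeR (2 lower at an unadjusted p under 0.05, DESeq2 1, limma-voom 0), with 1 lower when adjusted over the list alone (median -0.12, camera adjusted p = 0.272). Histone deacetylases and sirtuins had a median of -0.05 (0.939). Extracellular matrix genes had 1 called member of 20, Ccn2, a matricellular growth factor, which rose from 2.25 ± 0.183 to 9.72 ± 2.52 CPM, and the list was not called (median 0.12, camera adjusted p = 0.272).

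The remaining lists were not called by camera either. Lipogenesis had a median of 0.01 (camera adjusted p = 0.939, with the test pointing down), and it turned to a higher call without PA replicate 1 (2.71e-05) and a lower call without PA replicate 2 (1.32e-05). Gluconeogenesis and glycolysis had a median of 0.14 (0.272), ER protein folding of -0.26 (0.372), the circadian clock of 0.11 with a mean of -0.05 (0.584) and the acute phase response of -0.16 (0.372). ER protein folding was called without WT replicate 2 (0.000427) and without PA replicate 2 (0.00449), and the circadian clock without WT replicate 2 (0.00247). MHC class II presentation had a median of -0.34 (0.157; 0.0145 without PA replicate 2) and inflammatory cytokines of -0.34 (0.133). Pericentral and periportal hepatocyte genes had medians of 0.02 (0.939) and 0.33 (0.365). Markers of sinusoidal endothelium (-0.05, 0.509), stellate cells (-0.06, 0.939), cholangiocytes (0.16, 0.437), monocytes (-0.42, 0.125) and T and NK cells (-0.42, 0.584) were not called. Neutrophil, adipocyte and pancreatic acinar markers had 4, 3 and 2 tested members, too few for the list test, with medians of -0.94, 0.60 and -0.63. Among all lists of this paragraph edgeR and limma-voom called 0 members. Adjusted over the list alone, 1 member was lower in each of the lists of inflammatory cytokines, monocytes and pancreatic acinar cells, 1 adipocyte marker was higher, and 0 passed in the others. At an edgeR unadjusted p under 0.05, 5 periportal genes were higher and 5 lower (DESeq2 called 3 and 1), 2 acute phase genes were higher and 7 lower (DESeq2 1 and 3), and the others had at most 4 in a direction (DESeq2 at most 1).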

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

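The tests of a strain difference and of a male library were chosen only after the result was seen, and those of growth hormone induced genes, RSEM counts and alpha globins after the patterns they bear on had been seen but before their own values. The stranded count column that the comparisons did not use holds the minor share of reads in each library. In it, 9 genes were called higher and 13 lower in PA among 2958 tested with edgeR. Reads assigned to several genes in that column averaged 17778 per PA library (17266 and 18290) against 6280 per WT library (6264 and 6296).

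Lists of male-biased and of female-biased genes were both lower in PA by camera (adjusted p = 0.532 with an estimated correlation for each), with 7 male-biased genes called lower, and 6 female-biased genes called lower and 2 higher. With RSEM expected counts, which share out reads of near-identical genes, the called members had a median log2 fold change of -6.06. They had been picked by their calls in STAR counts and include genes outside the Mup and Cyp3a families. This median therefore cannot decide on reads shared between paralogs. In summed RSEM counts, WT exceeded PA 43.5-fold over the Mup genes and pseudogenes and 1410-fold over Cyp3a16, Cyp3a41a, Cyp3a41b and Cyp3a44. The falls of these families thus did not depend on leaving shared reads out. The summed CPM of 4 Y-linked genes reached at most 0.203 in a library, which argues against a male library. Of 16 male-biased members that are neither Mup nor Cyp3a genes, 6 were called lower and 0 higher, against 49 of 14339 other genes called lower (two-sided Fisher's exact test across genes, odds ratio 175, p = 1.86e-11). This test was written after those calls had been seen, and genes are not independent replicates, so its p-value is not support. The calls show only that the lower male-biased genes were not confined to those clusters. Of 24 such female-biased members 2 were called lower and 2 higher (odds ratio 26.5 for the lower calls, two-sided Fisher's exact p = 0.00325), so these members did not move one way and a strain difference at the Cyp3a cluster stays open for the female-biased list, as do strain differences elsewhere in the genome. Lower growth hormone signalling may be a cause, since the 6 growth hormone induced genes had a median of -0.927 and all 6 had lower values, led by Socs2 (-2.39) and Cish (-1.21). With all 4 libraries and genotype as the only term, edgeR called 0 of the 6 (2 at an unadjusted p under 0.05, DESeq2 2). Socs2 was at -1.65 without WT replicate 1, -2.87 without WT replicate 2 and -2.89 without PA replicate 2, and Cish at -1.365 without PA replicate 2.

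The calls include 2 genes near Pcca on chromosome 14, the only chromosome region tested in this way. Of 38 tested genes within 20 Mb of Pcca 2 were called, Dct (log2 fold change -6.40, and -7.055 without PA replicate 2, 4.48 Mb away) and Abcc4 (2.47, 3.83 Mb away), against 114 of 14362 elsewhere (two-sided Fisher's exact test across genes, p = 0.0375, odds ratio 6.94, 95% interval 0.80 to 27.5). A genomic segment carried along with the altered locus may account for these 2 calls, though the interval reaches below 1. It leaves the other 114 calls with a known position open.

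The beta globins Hbb-bs and Hbb-bt were lower in PA. The alpha globins Hba-a1 and Hba-a2, on another chromosome, had a median log2 fold change of -2.483, so less blood in the PA livers at collection is a candidate explanation. With all 4 libraries, edgeR with genotype as the only term called neither alpha globin (adjusted p = 0.107 and 0.122), while DESeq2 called both (0.000596 and 0.00525). The values depend on single libraries: without WT replicate 1 they were -1.87 and -1.80, and without PA replicate 2 they were -3.29 and -3.19. A change in red cells themselves stays open and was not tested.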

How the results depend on the processing

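The fit without mitochondrially encoded genes was chosen only after the result was seen. Pcca stayed lower and uncalled by its adjusted p under each of the 15 alternatives run for it, with log2 fold changes from -0.80 to -0.33. The 38 higher and 79 lower genes became 414 and 488 with no filter on low counts, where more genes were tested, 185 and 245 with DESeq2, and 50 to 239 and 105 to 261 when a library was left out; the cause was not tested. In the latter fits the lone sample of an arm is assumed to vary like the other group. With a replicate block they were 126 and 192, and 15 of the 16 lists were called, without the cell cycle list (camera adjusted p = 0.0666); deviations of same-numbered libraries from their group means correlated at -0.091. Whether the numbers mark a shared litter, day or batch is not in the labels and stays unknown. The other alternatives stayed within 1.5 times both counts, and limma-voom and RSEM counts shared 82 and 85 of the 117 genes. Of 40 lists, 16 were called with the preset correlation, 0 with an estimated correlation, 0 by fry and 14 to 17 under the others. Over the other settings, named genes kept direction and call in 1067 cases, gained a call in 71, lost it in 13 and turned in 5; with a library left out these were 353, 49, 7 and 15. Genes chosen after the result was seen are counted here too.

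Results that turned direction were not called with all 4 libraries. Cela2a, at 0 on the log2 scale, was 0.012 with upper-quartile factors, 0.013 with DESeq2, 0.006 in unstranded counts and 0.006 without mitochondrially encoded genes, and Mup20 was 0.018 with RSEM counts. With a library left out, log2 fold changes ran from -1.118 to 0.66 for Cela2a, -0.017 to 0.214 for Slc40a1, -0.845 to 0.005 for Fn1, -0.121 to 0.071 for Kdr and -0.354 to 0.208 for Rgs5. They ran from -0.135 to 0.376 for Ecm1, -0.964 to 0.047 for Tspan8, -0.575 to 1.035 for Gzma, -0.08 to 0.355 for Thy1, -0.453 to 0.566 for Jchain, -1.124 to 0.054 for Car3, -0.206 to 0.664 for mt-Cytb and -1.078 to 0.424 for Mup20. With RSEM counts, lipogenesis (camera adjusted p = 0.962), histone deacetylases and sirtuins (0.962) and stellate cell markers (0.962) turned. With a library left out, the camera adjusted p of lists that turned ran from 0.27 to 0.938 for mitochondrial fatty acid oxidation, 1.32e-05 to 0.734 for lipogenesis, 0.469 to 0.947 for bile acids and 0.000427 to 0.44 for ER protein folding. It ran from 0.00247 to 0.483 for the circadian clock, 0.0715 to 0.944 for the acute phase response, 0.283 to 0.794 for pericentral genes and 0.647 to 0.947 for stellate cell markers. Among these turned lists, the opposite direction passed the threshold for lipogenesis without PA replicate 1 (2.71e-05). The cause was not tested. Depth limits genes near 3 counts, such as Mup14 and Mup19 in PA.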

Other observations

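The genes named below and the list of fetal liver genes were chosen only after the result was seen.

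Some called genes stood outside the fixed lists; those named here were picked by hand, and no shared function was tested. Dio1, the deiodinase that activates thyroid hormone, fell from 222 ± 46.5 to 69.4 ± 6.04 CPM (SD, n = 2 each; log2 fold change -1.68, edgeR adjusted p = 0.0378, and 0.0958 without WT replicate 2). The sulfotransferase Sult2a8 fell from 816 ± 14.6 to 130 ± 4.01 CPM (log2 fold change -2.65), and the glycosyltransferase Ugt3a1 from 122 ± 3.10 to 16.9 ± 0.135 CPM (log2 fold change -2.85, edgeR adjusted p = 0.00179). Serpina12, which encodes vaspin, fell from 55.6 ± 12.8 to 1.58 ± 0.147 CPM. Slc10a2, the apical sodium-dependent bile acid transporter, fell from 34.2 ± 11.8 to 2.17 ± 2.02 CPM (log2 fold change -3.95, edgeR adjusted p = 0.0474, and 0.0529 with a CPM filter and 0.0592 with RSEM counts). Its log2 fold change was -3.24 without PA replicate 1 and -5.51 without PA replicate 2. The alcohol dehydrogenase Adh4 fell from 232 ± 55.3 to 74.0 ± 7.66 CPM (edgeR adjusted p = 0.047, and 0.15 without WT replicate 1 and 0.0514 with RSEM counts). Alpl, the tissue-nonspecific alkaline phosphatase, rose from 6.45 ± 0.0102 to 20.0 ± 2.97 CPM. H19, an imprinted non-coding RNA of fetal liver, rose from 0.065 and 0.236 CPM in the WT livers to 2.20 and 2.69 CPM in the PA livers (log2 fold change 4.04, edgeR adjusted p = 0.0286, and 3.35 without WT replicate 1 and 5.15 without WT replicate 2).

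Mup3 fell from 7470 ± 195 to 242 ± 130 CPM (log2 fold change -4.95, and -5.64 without PA replicate 2). Mup20, which encodes the male pheromone darcin, was at 65.8 ± 16.3 CPM in WT and 59.7 ± 40.6 CPM in PA (log2 fold change -0.14, edgeR adjusted p = 0.945). Its direction depends on single libraries, with -1.08 without PA replicate 1, 0.42 without PA replicate 2, 0.13 without WT replicate 1 and 0.02 with RSEM counts, called in none. Of 5 tested fetal liver genes, 3 had higher values in PA and edgeR called 0 (2 at an unadjusted p under 0.05; DESeq2 and limma-voom 0), with a median log2 fold change of 0.06. Across genes, which are not independent replicates, Spearman's correlation of the log2 fold change was 0.147 with GC content and -0.094 with exon length.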
